A study of Populus alba x Populus glandulosa with 12 samples.

How the data were processed

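The study measured RNA in leaves of wild-type 84K poplar at 0, 3, 6 and 9 days of drought, with 3 libraries per day, 12 in all. The tables deposited by the authors hold FPKM values, as their names state, and the values carry 2 decimals and sum to between 684857 and 732119 per library. Reads were not used here, and the aligner, the genome build and the program that computed FPKM are not given in the sources used here. The table of all genes lists 85392 gene models, with 4 columns of group means that equalled the means of the libraries within 0.01 for 100% of values. Of these models 26975 were at 0 in all libraries. Further deposited tables hold subsets of genes for each day. The tables for days 3 and 6 were identical byte for byte, with 5882 genes, and the table for day 9 held 18590, of which 4908 were shared. Of the genes in the table given for both day 3 and day 6, 96.2% had group means that differed at least 2-fold between days 3 and 0, and 86.2% between days 6 and 0. Genes at 0 on both days of a comparison were left out of its share. The subset tables were not used for any comparison.

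Samples were grouped by the day in their labels. The labels give each day its own batch, so batch and group cannot be told apart. The series text calls the replicates biological, and nothing states that they came from separate plants. No read counts or library sizes were used here. Relative depth was therefore read from the spacing of low FPKM values, as the most frequent ratio to the first control library, and lay between 0.956 and 1.14 on day 0, 0.923 and 1.01 on day 3, 0.892 and 0.940 on day 6, and 0.986 and 1.11 on day 9.

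Values were analysed as log2(FPKM + 1) for the 40736 genes with an FPKM of at least 1 in at least 3 of the 12 libraries. A linear model with 1 mean per day was fitted to all libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance moderation. Days 3, 6 and 9 were each compared with day 0, and day 6 with day 3 and day 9 with day 6 as tests of whether the changes against day 0 differed between days. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05 with no minimum change. An estimated correlation in the list tests and the replicate block used statmod 1.5.0. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

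Genes were named by the KEGG orthology (KO) names in the tables, which 29172 genes carry, 18891 of them tested; 0 genes had a description. The lists of genes covered abscisic acid synthesis, breakdown (CYP707A), receptors (PYL), PP2C phosphatases and transcription factors (ABF); osmolyte synthesis; aquaporins; heat shock proteins; proteasome and autophagy; antioxidant enzymes; glutathione transferases; light-harvesting antenna; photosystem subunits; carbon fixation; chlorophyll synthesis and breakdown; starch and sugar; ethylene; jasmonate; auxin; defence proteins; flavonoids; lignin and secondary wall; wall loosening; cuticle; cell cycle and histones; cytosolic and organelle-type ribosomes; the circadian clock; and markers of guard cells, vascular tissue and the plastid genome. Their topics were fixed before the data were examined, as were the comparisons and the main alternatives. The KO names that stand for each topic were chosen after the annotation was seen but before the change of any gene. The list planned for the plastid ribosome holds organelle-type KO names, most of which also name mitochondrial ribosomal proteins, and the tables do not tell these apart. A list of LEA proteins matched no KO name and was not analysed here. Lists with at least 5 tested members were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over all lists and the 3 days, and again with a correlation estimated from the data. limma's fry, which tests a list by itself, was run beside it with the same adjustment, and its result is given for some lists only. Counts adjusted over the list alone use the p-values of the members only.

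Named genes were chosen by rule. For each day they are the 5 largest called rises and the 5 largest called falls with a KO name, without overlap between the groups and with a mean of at least 5 FPKM in the higher group, 1 per name. For each list that passed limma's camera, up to 10 lists a day by p, they also include the called member with the largest rise and the called member with the largest fall. For day 9 against day 6 they are the 5 genes with the smallest adjusted p in each direction. Members of KO groups named in the text beside these serve as examples of a list.

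The procedure was tested on 1 simulated data set for the comparison of day 3 with day 0. In it 100 genes were given a log2 change of 1 and another 100 a log2 change of 2. All of these had a mean of at least 5 FPKM on day 0, so the shares recovered do not cover lower genes. The procedure recovered 88% of genes given a log2 change of 1 and 98% of those given 2. It called 9 unchanged genes, with 38542 genes tested in all. Of 100 random lists, 3 had a p under 0.05 in limma's camera, and a raised list of 20 genes had a p of 3.27e-74. Each gene was drawn by itself, so these lists held no correlation between genes. The check thus cannot show how often correlated members of real lists give false calls. The overlap of called genes between days was set beside the number expected for independent lists, n1 × n2 / N within each direction, and beside 20 simulations of unchanged groups that shared the control libraries.

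The alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling, a minimum log2 change of 1, fits to the 6 libraries of a comparison, a replicate block, leaving out each library in turn, and for lists an estimated correlation and a mean of at least 5 FPKM. That mean was taken over all 12 libraries, so a gene can pass through its values under drought alone. List results under it therefore depend in part on the changes themselves and are no independent check. The FPKM values were used as deposited in the main analysis because the authors had already scaled them. After the data were examined, 4 more were added: leaving out 661 genes that share all values with another gene together with genes listed at 0 in 1 library and at 20 FPKM or more in another of the same day; the lists tested for the steps between days; the pathways named in the tables, with at least 10 tested genes; and median-ratio scaling of the named genes in all 5 comparisons. Identifiers begin with Pag.A for 44998 models and Pag.B for 40394, and reads shared between such copies were not separated here.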

Results

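Leaf RNA of wild-type 84K poplar, a hybrid of Populus alba and Populus glandulosa, was sequenced before drought (day 0, the control, labelled CK) and on days 3, 6 and 9 of drought, with 3 libraries per day and 12 in all. The values were FPKM for 85392 gene models. Of these, 40736 reached an FPKM of 1 in at least 3 libraries and were tested. The number of genes with an FPKM of at least 1 was 38059.7 ± 86.6 (SD, n = 3) on day 0, 37725.3 ± 36.6 on day 3, 34599.3 ± 99.0 on day 6 and 35459.3 ± 331 on day 9. The FPKM sum per library lay between 684857 and 732119. The most abundant gene on days 0 and 3 was Pag.A01G004426.v3.1, which has no name in the tables, at 6489 ± 13.9 and 8460 ± 444 FPKM. On days 6 and 9 it was a gene named WHY1 (Pag.B08G000961.v3.1), at 14435 ± 184 and 13877 ± 580 FPKM.

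Across the tested genes, the mean Pearson r between libraries was 0.897 for day 0 against day 3, 0.653 for day 0 against day 6 and 0.649 for day 0 against day 9. Libraries of days 6 and 9 had a mean r of 0.964 with each other, near the values within a day (0.970 to 0.975). These r are taken across genes, which are not independent replicates. Nothing states that the 3 libraries of a day came from separate plants, so the p-values measure the spread between these samples, which may be technical. The labels give each day its own batch, so batch and day cannot be told apart in any comparison of days. No plants without drought were sampled on days 3, 6 or 9. Changes against day 0 therefore cannot tell drought apart from the time that passed. Changes are differences of log2(FPKM + 1), a scale that understates the change of low genes, and "rose" and "fell" refer to an adjusted p under 0.05 from limma.

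**Figure D1:**
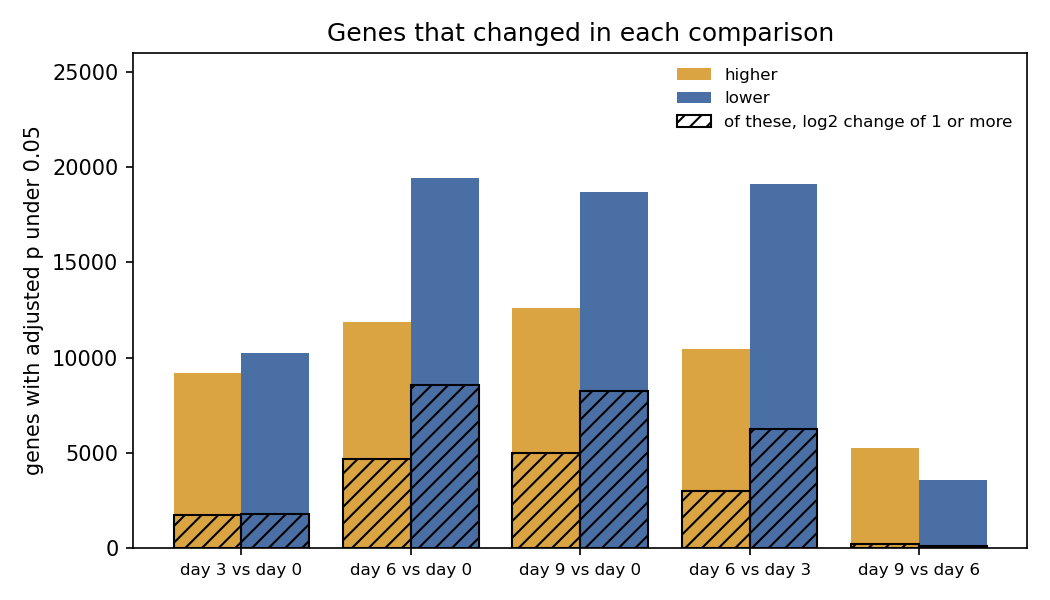
Number of genes with an adjusted p under 0.05 from limma (vertical axis) that were higher or lower in each comparison of days, with the hatched part showing those that also changed by at least 1 on the log2 scale. After 3 days 9191 genes were higher and 10255 lower than on day 0, after 6 days 11885 were higher and 19407 lower with the values as deposited, and with median-ratio scaling 15345 were higher and 15561 lower; for day 9 against day 6 the larger side turns with that scaling, from 5275 higher and 3556 lower to 4136 higher and 4888 lower.

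The comparison of day 3 with day 0 asks how leaf transcripts differed early in drought. The transcript named NCED (Pag.B11G000660.v3.1), for the 9-cis-epoxycarotenoid dioxygenase that makes the committed step of abscisic acid synthesis, rose from 1.04 ± 0.273 to 94.5 ± 2.3 FPKM (SD, n = 3), a log2 change of 5.55 (SE 0.08). A beta-carotene hydroxylase (crtZ, Pag.B04G000763.v3.1), from the pathway that supplies the carotenoid precursors of that hormone, rose from 0.47 ± 0.111 to 94.7 ± 6.94 FPKM, the largest rise of a named gene on this day. A homeodomain-leucine zipper transcription factor (HD-ZIP, Pag.B14G000966.v3.1) went from 5.13 ± 0.314 to 226 ± 5.45 FPKM, and a nucleoredoxin (NXN, Pag.A02G002608.v3.1) from 6.09 ± 0.528 to 172 ± 3.48 FPKM.

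Among the largest falls on day 3 was a peroxiredoxin (PRDX6, Pag.A08G001560.v3.1), which fell from 556 ± 17.3 to 23.2 ± 1.49 FPKM, a log2 change of -4.53. Transcripts for 2 enzymes of the cell wall fell with it, a xyloglucan:xyloglucosyl transferase (XTH, Pag.B19G001494.v3.1) from 92.4 ± 2.87 to 3.88 ± 0.560 FPKM and a pectinesterase (Pag.A06G001614.v3.1) from 24.3 ± 1.71 to 0.417 ± 0.311 FPKM. A sorbitol dehydrogenase (SORD, Pag.A12G002074.v3.1) fell from 60.1 ± 22.9 to 3.15 ± 1.94 FPKM, with an adjusted p of 5.31e-04 from limma. A glutaredoxin (GLRX, Pag.A08G000263.v3.1) was at 135.84, 158.28 and 163.86 FPKM on day 0 and listed at 0 in all 3 libraries of day 3, but also listed at 0 in 1 library of day 6 and 1 of day 9, with its other values there between 64.72 and 259.07 FPKM. Its adjusted p of 0.0330 from limma rose to between 0.0726 and 0.0789 without any single library of day 0 or day 3, within a range of 2.15e-09 to 0.0789 over its alternatives.

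The protein phosphatases 2C, negative regulators of abscisic acid signalling, rose as a group on day 3: 25 of 28 tested members rose, none fell and 3 did not pass (27 rose adjusted over the list alone), with a median log2 change of 2.17. The member named PP2C with the largest rise, Pag.A09G000383.v3.1, went from 2.34 ± 0.150 to 91.7 ± 0.690 FPKM. The list passed limma's camera at an adjusted p of 4.73e-18, and at an adjusted p = 0.0103 with an estimated correlation. Among the enzymes that degrade the hormone, the CYP707A group, 6 of 12 rose and 2 fell (median 0.64, adjusted p of 0.00915 from limma's camera, adjusted p = 0.0650 with an estimated correlation). The median of that list was 1.73 among genes with a mean FPKM of at least 5. Of 26 genes named ABF, transcription factors that act in abscisic acid responses, 15 rose, 3 fell and 8 did not pass (16 rose and 3 fell adjusted over the list alone), with a median of 0.32 (1.04 among genes with a mean FPKM of at least 5) and an adjusted p of 7.97e-06 from limma's camera (adjusted p = 0.0438 with an estimated correlation). ABF Pag.A04G001436.v3.1 rose from 8.50 ± 0.399 to 45.5 ± 1.1 FPKM. ABF Pag.A10G002611.v3.1 fell by 0.17 on the log2 scale, from 6.48 ± 0.174 to 5.64 ± 0.215 FPKM. The list of abscisic acid synthesis enzymes was mixed, with 7 of 22 rising and 8 falling (9 fell adjusted over the list alone): 4 of 8 NCED genes rose, and all 4 genes of the aldehyde oxidase AAO3 fell with a median of -1.01. Its median was -0.02 (0.17 among genes with a mean FPKM of at least 5) while its mean was 0.49 and its test pointed up, and it did not pass limma's camera (adjusted p of 0.801). The PYL receptors did not pass either, with 4 of 22 rising and 10 falling (5 and 10 adjusted over the list alone), a median of -0.24 and an adjusted p of 0.188 from limma's camera. With 1 library left out at a time their median lay between -0.31 and -0.03. Their median turned to 0.13 and their test turned up among genes with a mean FPKM of at least 5.

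Enzymes that make protective sugars and proline, the osmolyte list, were the next strongest rise: 27 of 38 rose, 7 fell and 4 did not pass on day 3 (27 and 8 adjusted over the list alone), with a median log2 change of 1.26 (2.11 among genes with a mean FPKM of at least 5). All 4 inositol-3-phosphate synthase genes (INO1) rose, with a median of 3.01, as did 10 of 14 galactinol synthase genes (GOLS), 9 of 14 raffinose synthase genes and both stachyose synthase genes. GOLS Pag.B10G001423.v3.1 rose from 3.31 ± 0.792 to 103 ± 4.38 FPKM, and a raffinose synthase (Pag.A11G001788.v3.1) fell from 6.74 ± 0.281 to 1.95 ± 0.220 FPKM. The list passed limma's camera at an adjusted p of 6.64e-09, and at an adjusted p = 0.00371 with an estimated correlation. Flavonoid enzymes rose in 19 of 23 cases and fell in 0 (median 0.67), including all 6 chalcone synthase (CHS) and all 3 DFR genes. The leucoanthocyanidin reductase LAR Pag.A10G001481.v3.1 rose from 3.21 ± 0.601 to 20.1 ± 2.78 FPKM. Their adjusted p from limma's camera was 4.50e-06, and adjusted p = 0.0438 with an estimated correlation.

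Heat shock proteins rose in 51 of 103 cases and fell in 5 (median 0.28), among them 20 of 42 small heat shock proteins (HSP20), which fell in 0 cases. HSP20 Pag.A08G001905.v3.1 was at 0, 0 and 1.07 FPKM on day 0 and 5.57 ± 1.00 FPKM on day 3, and the chaperonin groEL Pag.A10G001529.v3.1 fell by 0.28 on the log2 scale. Proteasome and autophagy genes rose in 74 of 202 cases and fell in 21, by a small median of 0.08, with 14 of 21 ATG8 genes, which build the autophagosome, among the rises. Both lists passed limma's camera, at adjusted p of 3.72e-05 and 0.00867, and at an adjusted p = 0.0103 and an adjusted p = 0.0195 with an estimated correlation. The proteasome and autophagy call was lost among genes with a mean FPKM of at least 5.

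Genes of chlorophyll breakdown rose in 10 of 16 cases and fell in 2 on day 3 (median 1.1), with both NOL/NYC1 genes for chlorophyll b reductase and 5 of 7 stay-green genes (SGR) rising. The list had an adjusted p of 2.53e-04 from limma's camera and an adjusted p = 0.0721 with an estimated correlation. Starch breakdown enzymes and sugar carriers rose in 29 of 83 cases and fell in 21 (30 and 21 adjusted over the list alone; median 0.07), with 7 of 11 alpha-amylase genes rising. That list passed limma's camera at an adjusted p of 0.0336, with an adjusted p = 0.276 with an estimated correlation, and at 0.0681 without the first library of day 3 it no longer passed. Its median was 0.03 without that library, 0.05 without library 3 of day 0 and 0.19 among genes with a mean FPKM of at least 5.

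The apparatus of photosynthesis fell by modest amounts on day 3. Of 49 genes for light-harvesting antenna proteins, 43 fell, 1 rose and 5 did not pass (45 fell adjusted over the list alone), with a median log2 change of -0.89. LHCB7 Pag.A05G002610.v3.1 was the member that rose, by 0.18, from 19.1 ± 0.396 to 21.7 ± 0.587 FPKM. LHCB2 Pag.A02G000527.v3.1 fell, but unevenly, from 80.3, 34.14 and 57.32 FPKM on day 0 to 37.06, 0 and 0.01 on day 3. Photosystem subunits fell in 45 of 67 cases and rose in 4 (5 and 45 adjusted over the list alone; median -0.39), psaG Pag.A11G001807.v3.1 falling from 22.7 ± 4.01 to 4.15 ± 1.1 FPKM and psbR Pag.B01G004493.v3.1 rising from 45.6 ± 3.65 to 62.9 ± 5.21 FPKM. Carbon fixation enzymes fell in 16 of 18 cases (median -0.73), with the Rubisco small subunit rbcS Pag.B04G001039.v3.1 at 419 ± 19.2 FPKM on day 0 and 133 ± 2.38 on day 3. Chlorophyll synthesis genes fell in 29 of 48 cases and rose in 3 (4 and 30 adjusted over the list alone; median -0.38), chlorophyllide a oxygenase CAO Pag.B02G000900.v3.1 falling from 35.6 ± 2.55 to 5.24 ± 0.419 FPKM. In contrast, hemA Pag.B09G000812.v3.1, for the glutamyl-tRNA reductase at the start of the pathway, rose from 3.48 ± 0.334 to 6.77 ± 0.332 FPKM. Adjusted p from limma's camera were 4.46e-13 for the antenna, 4.09e-06 for the photosystems, 3.91e-08 for carbon fixation and 1.59e-05 for chlorophyll synthesis. In the same order these were an adjusted p = 0.136, 0.344, 0.0365 and 0.137 with an estimated correlation.

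Ribosomal protein, wall-loosening and auxin-response lists also passed limma's camera as lower. Cytosolic ribosomal proteins fell in 290 of 427 cases and rose in 9 on day 3 (9 and 297 adjusted over the list alone), by a median of -0.29. RPL30 Pag.A05G000832.v3.1 fell by 0.85 on the log2 scale, and RPS23 Pag.A08G002090.v3.1 rose by 1.02. Ribosomal proteins of the organelle type, whose KO names cover the plastid and the mitochondrion alike, fell in 56 of 153 cases and rose in 10 (9 and 55 adjusted over the list alone; median -0.16). Wall-loosening enzymes fell in 30 of 56 cases and rose in 12 (median -0.36). Their median was -0.22 without library 2 of day 0, -0.23 without library 3 and -0.60 among genes with a mean FPKM of at least 5. Auxin-response genes fell in 61 of 127 cases and rose in 15 (median -0.39), with 30 of 47 Aux/IAA repressor genes falling. In limma's camera the adjusted p were 2.08e-14, 0.00867, 0.00179 and 2.09e-04 in that order, and an adjusted p = 0.140, 0.175, 0.116 and 0.117 with an estimated correlation. Circadian clock genes fell in 18 of 34 cases and rose in 7 (9 and 18 adjusted over the list alone; median -0.25), all 4 LHY, all 4 ELF3 and all 4 PRR7 genes falling, with an adjusted p of 0.0191 from limma's camera and an adjusted p = 0.292 with an estimated correlation. The clock call was lost among genes with a mean FPKM of at least 5, where the median was -0.07. The hour of sampling is not given in the sources used here.

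In all, 19446 genes passed limma's test on day 3, 9191 higher and 10255 lower, and 3517 of them changed by at least 1 on the log2 scale. The values of the 3 drought and 3 control libraries did not overlap for 57.4% of the tested genes, where chance gives 10%. Of the genes named above, LHCB7, LHCB2, ABF Pag.A10G002611.v3.1 and groEL also lost their call in at least 1 alternative, without the first library of day 0 in each case; their adjusted p over all alternatives reached 0.0540, 0.130, 0.123 and 0.0960.

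The comparison of day 6 with day 0 asks the same question later in the drought. LHCB1 Pag.B05G002421.v3.1, an antenna protein of photosystem II, fell from 635 ± 33.5 to 1.22 ± 0.839 FPKM (SD, n = 3), and LHCB2 Pag.B14G001625.v3.1 from 453 ± 8.76 to 0.773 ± 0.150 FPKM, log2 changes of -8.25 (SE 0.43) and -8.0 (SE 0.07). All 49 antenna genes fell, with a median of -4.47. Of 67 photosystem subunits 66 fell and 1 did not pass (median -3.51), and psaG Pag.B11G000022.v3.1 went from 113 ± 8.70 FPKM to being listed at 0 in all 3 libraries. Carbon fixation genes fell in 17 of 18 cases (median -2.75), with rbcS Pag.B04G001039.v3.1 at 7.35 ± 0.447 FPKM. The exception was a phosphoribulokinase gene, PRK Pag.B01G001412.v3.1, which rose from 9.34 ± 0.398 to 18 ± 0.652 FPKM.

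Chlorophyll synthesis genes fell in 40 of 48 cases and rose in 5 on day 6 (median -2.51). A protochlorophyllide reductase (por, Pag.B01G004254.v3.1) fell from 97.3 ± 4.14 to 0.650 ± 0.305 FPKM. hemA Pag.A09G000810.v3.1 rose from 2.18 ± 0.409 to 18.3 ± 1.17 FPKM, 1 of 4 hemA genes that rose. In the opposite direction, chlorophyll breakdown genes rose in 13 of 16 cases and fell in 2 (median 1.97), the stay-green gene SGR Pag.B01G001209.v3.1 rising from 3.98 ± 0.777 to 47.1 ± 1.62 FPKM. Organelle-type ribosomal proteins, of plastids and mitochondria together, fell in 121 of 153 cases and rose in 5 (median -0.87, and -1.35 among genes with a mean FPKM of at least 5), rpmA Pag.B01G003417.v3.1 falling from 39.3 ± 2.93 to 3.19 ± 0.301 FPKM and rpmD Pag.B14G001526.v3.1 rising from 7.79 ± 0.974 to 15.9 ± 0.225 FPKM. The adjusted p of these lists in limma's camera were 1.31e-16 for the antenna, 5.70e-17 for the photosystems, 4.43e-06 for carbon fixation, 3.56e-07 for chlorophyll synthesis, 2.14e-05 for chlorophyll breakdown and 2.94e-08 for the organelle-type ribosome. In the same order these were an adjusted p = 0.0998, 0.117, 0.0564, 0.0976, 0.0564 and 0.0295 with an estimated correlation, and the median of each list kept its sign with median-ratio scaling (-4.27, -3.26, -2.51, -2.33, 2.21 and -0.70).

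**Figure D2:**
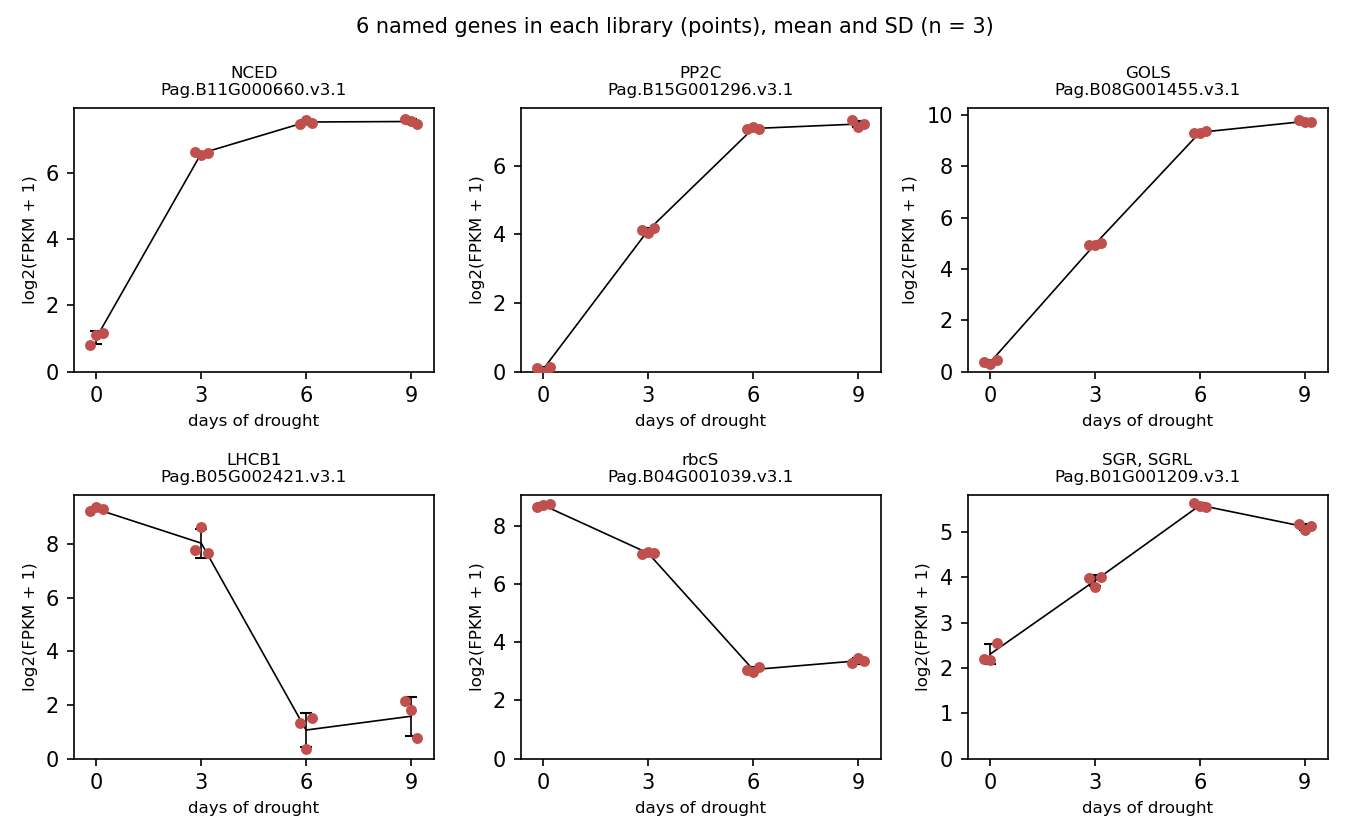
Values of 6 genes on the log2(FPKM + 1) scale (vertical axis) against the day of drought (horizontal axis), each point a library, with the mean and SD of 3 libraries. NCED (1.04, 94.5, 183 and 185 FPKM on days 0, 3, 6 and 9), PP2C, GOLS and SGR rise in the plot, LHCB1 and rbcS fall, and day 9 lies close to day 6 in each panel.

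The 5 largest rises of named genes on day 6 started from means between 0.233 and 46.6 FPKM on day 0. A galactinol synthase, GOLS Pag.B08G001455.v3.1, rose from 0.290 ± 0.0656 to 639.7 ± 14 FPKM, a log2 change of 8.96 (SE 0.04, adjusted p of 1.29e-16 from limma), and a SWEET sugar carrier (Pag.A01G000814.v3.1) from 0.233 ± 0.101 to 580.4 ± 17.0 FPKM. The gene named WHY1 (Pag.B08G000961.v3.1) rose from 46.6 ± 3.00 to 14435 ± 184 FPKM, a cinnamyl-alcohol dehydrogenase (Pag.B06G001593.v3.1) from 11.2 ± 0.551 to 3599 ± 30.1 FPKM, and a gene named CST3 (Pag.B02G002510.v3.1) from 2.88 ± 0.650 to 688 ± 9.02 FPKM. Taking 1 gene per KO name by the rule above, the largest falls beside the antenna genes were PRDX6, which was listed at 0 in all 3 libraries, the auxin-response gene SAUR Pag.A04G001679.v3.1, from 199 ± 5.39 FPKM to 0, 0 and 0.16, and a terpene synthase (GERD, Pag.B08G000021.v3.1), from 218 ± 14.2 to 0.207 ± 0.107 FPKM.

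Osmolyte genes rose in 30 of 38 cases and fell in 6 on day 6, with a median log2 change of 2.80. Of 14 galactinol synthase genes 10 rose, and so did 12 of 14 raffinose synthase genes (median 2.91). GOLS;PANK Pag.A08G000608.v3.1 fell from 107 ± 2.72 to 8.65 ± 0.140 FPKM. Protein phosphatases 2C rose in 22 of 28 cases and fell in 3 (median 2.73). PP2C Pag.B15G001296.v3.1, at 0.07, 0 and 0.09 FPKM on day 0, reached 135 ± 2.95 FPKM, and PP2C;STK38 Pag.A06G000102.v3.1 fell from 29.2 ± 0.788 to 20.4 ± 1.36 FPKM. Heat shock proteins rose in 48 of 103 cases and fell in 27, with a median of 0.20 (0.38 with median-ratio scaling). Proteasome and autophagy genes rose in 82 of 202 and fell in 47 (82 and 46 adjusted over the list alone), with a median of 0.08 (0.31 with median-ratio scaling). By limma's camera these lists had adjusted p of 1.27e-10, 4.47e-10, 0.00225 and 0.00365, and an adjusted p = 0.0028, 0.0365, 0.0253 and 0.0134 with an estimated correlation. The heat shock and the proteasome and autophagy calls were lost among genes with a mean FPKM of at least 5.

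Other rises on day 6 lost their call with an estimated correlation. Flavonoid genes rose in 17 of 23 cases and fell in 2 (median 1.23), LAR Pag.A10G001481.v3.1 reaching 56.4 ± 2.91 FPKM and a chalcone isomerase (Pag.B19G000868.v3.1) falling from 45.9 ± 2.12 to 9.55 ± 0.674 FPKM. ABF genes rose in 16 of 26 cases and fell in 6 (median 0.61, and 0.96 among genes with a mean FPKM of at least 5). Ethylene genes rose in 28 of 49 cases and fell in 16 (median 0.47), including 4 of 5 genes named ACS1_2_6 for the enzyme that makes the ethylene precursor (median 2.98) and 10 of 16 ethylene receptor genes. The test of these lists by limma's camera gave adjusted p of 5.45e-05, 0.00161 and 0.00262, and an adjusted p = 0.0564, 0.0976 and 0.0650 with an estimated correlation. The flavonoid call was also lost among genes with a mean FPKM of at least 5.

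Other lists that passed as lower on day 6 covered PYL receptors, auxin response, wall loosening, the cell cycle, antioxidant enzymes and cytosolic ribosomes. PYL abscisic acid receptors fell in 19 of 22 cases and rose in 2 (median -1.04). Auxin-response genes fell in 78 of 127 cases and rose in 30 (median -1.12), with 39 of 47 Aux/IAA genes and 13 of 16 PIN auxin carrier genes falling but 8 of 14 GH3 genes rising. Wall-loosening genes fell in 39 of 56 cases and rose in 15 (median -1.07, and -1.82 among genes with a mean FPKM of at least 5). Cell cycle and histone genes fell in 70 of 101 cases and rose in 13 (71 fell adjusted over the list alone; median -0.74), with 17 of 20 histone H4 genes falling. Antioxidant enzymes fell in 50 of 65 cases and rose in 12 (median -0.78), with 10 of 11 SOD1 genes, all 6 SOD2 genes and all 5 peroxiredoxin Q genes falling. Cytosolic ribosomal proteins fell in 315 of 427 cases and rose in 16 (316 fell adjusted over the list alone; median -0.40), and with median-ratio scaling 212 fell and 73 rose (median -0.17). RPL10 Pag.B13G001556.v3.1 rose from 64.3 ± 3.95 to 181 ± 7.58 FPKM, and RPS15 Pag.A02G002363.v3.1 fell from 27.81, 19.43 and 35.19 FPKM to 0, 0 and 5.9. Adjusted p from limma's camera were 0.0109, 0.0245, 0.0283, 0.00658, 0.00881 and 4.38e-06 in that order, and an adjusted p = 0.0638, 0.292, 0.246, 0.179, 0.220 and 0.342 with an estimated correlation. The receptor call was lost among genes with a mean FPKM of at least 5, where the median was -0.44.

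On day 6 limma called 31292 genes, 11885 higher and 19407 lower than on day 0, and 13230 of them changed by at least 1 on the log2 scale. The values did not overlap for 79.4% of tested genes, where chance gives 10%. The median log2 change of all tested genes was -0.21 on day 6 and -0.18 on day 9, and median-ratio scaling moved it by 0.21 and 0.17 to -0.01 on both days, so list medians on these days are to be read against that shift. With this scaling, 15345 genes were higher and 15561 lower on day 6, that is 49.7% of the calls higher where the deposited values gave 38.0%. None of the lists called on day 6 turned direction with it. Of the 65 named genes 63 were called on day 6 and 2 of these turned: RAV Pag.B08G001291.v3.1, with a log2 change of -0.10, went to 0.15 and was called higher, and PP2C Pag.A18G001005.v3.1, at -0.20, went to 0.02 and did not pass.

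**Figure D3:**
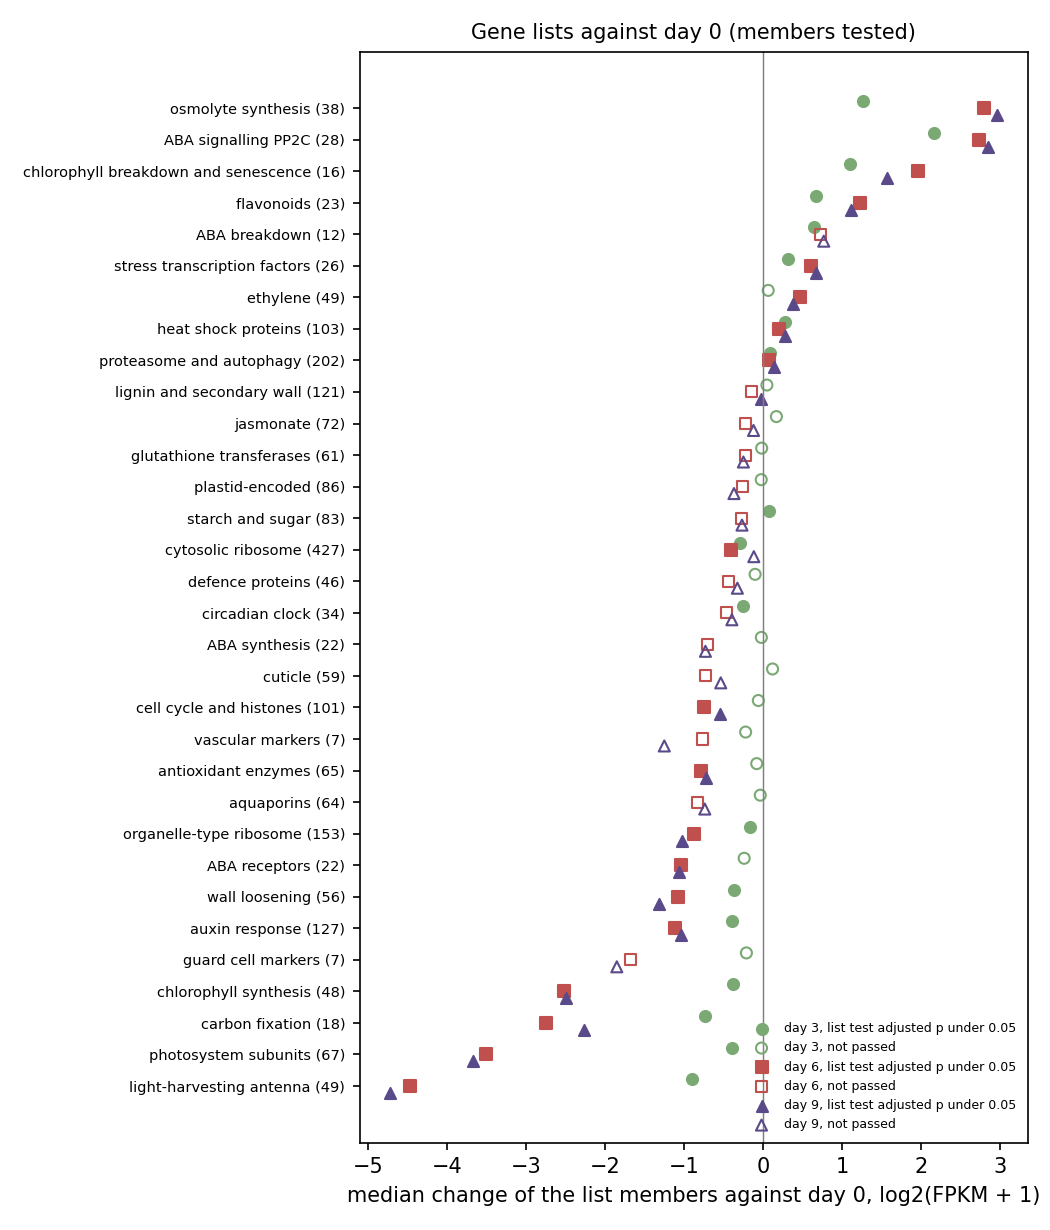
Median log2 change against day 0 (horizontal axis) of each gene list (vertical axis) on days 3, 6 and 9, filled where limma's camera gave an adjusted p under 0.05 and open where it did not. The antenna and photosystem lists lie farthest to the left on days 6 and 9 (-4.47 and -3.51 on day 6), the PP2C and osmolyte lists farthest to the right, and with median-ratio scaling the medians of the glutathione transferase and jasmonate lists on day 6 and of the jasmonate, lignin and cytosolic ribosome lists on day 9 turn from negative to positive.

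The comparison of day 9 with day 0 gave much the same picture as day 6. GOLS Pag.B08G001455.v3.1 reached 859 ± 28 FPKM (SD, n = 3; log2 change 9.38, SE 0.04), the SWEET carrier Pag.A01G000814.v3.1 535 ± 18.6, the cinnamyl-alcohol dehydrogenase 2881 ± 167, and CST3 669 ± 70.3 FPKM. LHCB2 Pag.B14G001625.v3.1 stood at 0.503 ± 0.112 FPKM and LHCB1 Pag.B05G002403.v3.1 fell from 631 ± 20.7 on day 0 to 1.34 ± 0.731 FPKM. PRDX6 was again listed at 0 in all 3 libraries, SAUR Pag.A09G001222.v3.1 went from 184 ± 1.54 FPKM to 0, 0.21 and 0, and the terpene synthase GERD stood at 0.680 ± 0.0917 FPKM.

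All 49 antenna genes (median -4.72), 65 of 67 photosystem subunits (median -3.66), 17 of 18 carbon fixation genes (median -2.27) and 40 of 48 chlorophyll synthesis genes (median -2.50) fell on day 9, and 0, 0, 1 and 6 rose. The Rubisco small subunit rbcS Pag.A04G001052.v3.1 fell from 493 ± 16.1 to 9.55 ± 1.16 FPKM, and PRK Pag.B01G001412.v3.1 rose to 23.2 ± 1.59 FPKM. Chlorophyll breakdown genes rose in 12 of 16 cases and fell in 2 (median 1.57), SGR Pag.A01G001309.v3.1 rising from 0.340 ± 0.0624 to 9.36 ± 0.312 FPKM. Organelle-type ribosomal proteins, of plastids and mitochondria together, fell in 98 of 153 cases and rose in 11 (median -1.03). In limma's camera the adjusted p were 6.00e-17, 3.13e-17, 4.50e-06, 3.07e-07, 1.80e-04 and 4.36e-06 in that order, and an adjusted p = 0.0976, 0.117, 0.0564, 0.0976, 0.0671 and 0.0494 with an estimated correlation.

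Osmolyte genes rose in 32 of 38 cases and fell in 6 on day 9 (median 2.97), now including all 4 P5CS genes, whose enzyme makes proline. Protein phosphatases 2C rose in 21 of 28 cases and fell in 5 (median 2.85), PP2C Pag.B15G001296.v3.1 reaching 148 ± 10.4 FPKM and PP2C Pag.A18G001005.v3.1 falling from 11.1 ± 0.341 to 6.74 ± 0.493 FPKM. Heat shock proteins rose in 52 of 103 cases and fell in 24, with a median of 0.28 (0.43 with median-ratio scaling). HSP20 Pag.B10G001862.v3.1 went from 0.11, 0.23 and 0 FPKM to 33.2 ± 0.960, and groEL Pag.B10G001293.v3.1 fell from 24.2 ± 0.829 to 2.4 ± 0.597 FPKM. Proteasome and autophagy genes rose in 100 of 202 cases and fell in 49 (100 and 47 adjusted over the list alone), with a median of 0.14 (0.33 with median-ratio scaling). The adjusted p of these lists in limma's camera were 2.46e-11, 1.1e-08, 3.70e-04 and 0.00172, and an adjusted p = 0.0028, 0.0438, 0.0134 and 0.0103 with an estimated correlation.

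Flavonoid genes rose in 18 of 23 cases and fell in 2 on day 9 (19 and 2 adjusted over the list alone; median 1.1). ABF genes rose in 18 of 26 and fell in 6 (median 0.67), and ethylene genes rose in 26 of 49 and fell in 16 (median 0.38). Lignin and secondary wall genes rose in 53 of 121 cases and fell in 47, including rises of all 8 cinnamoyl-CoA reductase genes (CCR) and 13 of 21 4CL genes and falls of 16 of 24 HCT genes. Their median was -0.02 while their mean was 0.47 and their test pointed up, and with median-ratio scaling the median turned to 0.15 and the list no longer passed. The median turned to 0.54 and the list passed among genes with a mean FPKM of at least 5. The median also turned, to between 0.03 and 0.13, without any single library of day 0, without the first or second of day 3 or without the second of day 9, and was -0.03 and -0.04 without libraries 1 and 3 of day 9. By limma's camera these lists had adjusted p of 5.93e-05, 0.00108, 0.0197 and 0.0358, and an adjusted p = 0.0564, 0.0942, 0.117 and 0.284 with an estimated correlation. The flavonoid call was lost among genes with a mean FPKM of at least 5.

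The other falls of day 9 were those of day 6 without the cytosolic ribosome. PYL receptors fell in 19 of 22 cases and rose in 3 (median -1.07), and auxin-response genes fell in 79 of 127 and rose in 34 (median -1.03). Wall-loosening genes fell in 39 of 56 and rose in 15 (median -1.31, and -2.03 among genes with a mean FPKM of at least 5), cell cycle and histone genes fell in 63 of 101 and rose in 12 (median -0.55), and antioxidant enzymes fell in 48 of 65 and rose in 11 (median -0.72). The test of these lists by limma's camera gave adjusted p of 0.0142, 0.0142, 0.0116, 0.0114 and 0.00657, and an adjusted p = 0.0671, 0.266, 0.183, 0.209 and 0.205 with an estimated correlation. The receptor call was lost without the second library of day 0 (adjusted p of 0.0650 from limma's camera) and among genes with a mean FPKM of at least 5, where the median was -0.45. Cytosolic ribosomal proteins did not pass on day 9, with 95 of 427 rising and 194 falling (90 and 194 adjusted over the list alone; median -0.11, adjusted p of 0.575 from limma's camera), and with median-ratio scaling the direction turned, with 169 rising, 111 falling and a median of 0.08.

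On day 9 limma called 31317 genes, 12595 higher and 18722 lower than on day 0, and 13181 of them changed by at least 1 on the log2 scale. With median-ratio scaling 15410 were higher and 15604 lower, that is 49.7% higher where the deposited values gave 40.2%. The values did not overlap for 79.2% of the tested genes, where chance gives 10%.

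Several lists did not pass limma's camera on some or all days. That test sets a list against all other genes, so a list that did not pass may still have changed by itself. CYP707A genes split evenly on days 6 and 9, with 6 of 12 rising and 6 falling each day (medians 0.73 and 0.77, adjusted p of 0.172 and 0.177). By limma's fry the CYP707A list passed as higher on both days, each at an adjusted p of 2.03e-12. Among genes with a mean FPKM of at least 5 the CYP707A list passed as higher on both days, with medians of 3.6 and 3.49. That mean includes the drought libraries, so it keeps genes that rose from low values more readily than genes that fell to them. Abscisic acid synthesis genes fell in 16 of 22 cases and rose in 6 on both days (medians -0.70 and -0.73, adjusted p of 0.406 and 0.340), and 4 of 8 NCED genes rose and 4 fell. limma's fry, which tests a list by itself, passed it as higher on these days (adjusted p of 2.34e-06 and 3.09e-06), where its median and limma's camera pointed down. Among genes with a mean FPKM of at least 5 limma's camera pointed up as well on both days, with medians of -0.40 and -0.32 and adjusted p of 0.683 and 0.746. Aquaporins rose in 24 of 64 cases and fell in 25 on day 3 (26 and 25 adjusted over the list alone; median -0.03, mean 0.10, test up), and fell in 43 and 38 cases on days 6 and 9 and rose in 18 and 23 (19 and 43 on day 6 adjusted over the list alone; medians -0.83 and -0.74). Their adjusted p were 0.622, 0.126 and 0.450, and 19 of 22 TIP genes, the vacuolar water channels, fell on day 6. By limma's fry the aquaporin list passed as higher on day 3 (adjusted p of 3.69e-06). It passed fry as lower on days 6 and 9 (adjusted p of 6.13e-10 and 5.35e-08). Among genes with a mean FPKM of at least 5 the aquaporin list passed as lower on day 6, with a median of -0.95, and on day 3 its median was -0.05 and its test turned down. Starch and sugar genes on days 6 and 9 rose in 27 and 29 of 83 cases and fell in 42 and 44 (medians -0.26 on both days, means 0.03 and 0.10, tests up with the deposited values and down with median-ratio scaling, adjusted p of 0.853 and 0.848), and the median of day 9 turned to 0.06 and that of day 6 was -0.01 among genes with a mean FPKM of at least 5. Clock genes fell in 19 and 18 of 34 cases and rose in 8 and 10 (medians -0.46 and -0.39, adjusted p of 0.151 and 0.271), and among genes with a mean FPKM of at least 5 they passed as lower on both days, with medians of -0.61 and -0.50.

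Jasmonate genes on days 3, 6 and 9 rose in 33, 30 and 32 of 72 cases and fell in 20, 37 and 35 (34 and 21 on day 3 adjusted over the list alone), with medians of 0.17, -0.21 and -0.12, the latter pair turning to 0.02 and 0.07 with median-ratio scaling. The tests pointed up on each day and had adjusted p of 0.0767, 0.622 and 0.50 from limma's camera, and 15, 14 and 14 of 21 JAZ repressor genes rose. The jasmonate median of day 3 was 0.36 among genes with a mean FPKM of at least 5, where the test of day 6 also turned down (adjusted p of 0.980 from limma's camera). By limma's fry the jasmonate list passed as higher on day 3 and as lower on day 6 (adjusted p of 2.61e-04 and 0.0112). It did not pass fry on day 9 (adjusted p of 0.608). Glutathione transferases rose in 23, 28 and 23 of 61 cases and fell in 15, 29 and 32, with medians of -0.01, -0.22 and -0.25, means of 0.18, -0.05 and -0.23 and tests pointing up on all 3 days with the deposited values (adjusted p of 0.170, 0.288 and 0.848 from limma's camera); with median-ratio scaling the median of day 6 turned to 0.14. Leaving out 1 library gave medians between -0.02 and 0.06 on day 3 and between -0.24 and 0.08 on day 6. By limma's fry the glutathione transferase list passed as higher on day 3 and as lower on day 9 (adjusted p of 5.40e-08 and 1.62e-06). It did not pass fry on day 6 (adjusted p of 0.923). The glutathione transferase medians of days 3 and 6 turned to 0.05 and 0.20 among genes with a mean FPKM of at least 5, and on day 9 the test turned down, with a median of -0.08. Lignin genes on days 3 and 6 rose in 39 and 50 of 121 cases and fell in 28 and 53 (41 and 28 on day 3 adjusted over the list alone), with medians of 0.05 and -0.15, a mean of 0.27 and an upward test on day 6, and adjusted p of 0.150 and 0.148 from limma's camera. Without single libraries the lignin median of day 6 lay between -0.31 and -0.03. Among genes with a mean FPKM of at least 5 the lignin list passed as higher on days 3 and 6, with medians of 0.14 and 0.60, so that the median of day 6 turned. Ethylene genes on day 3 rose in 21 of 49 cases and fell in 14 (21 and 15 adjusted over the list alone; median 0.07, and 0.23 among genes with a mean FPKM of at least 5, adjusted p of 0.167 from limma's camera). The ethylene median over all tested members lay between 0.05 and 0.17 when 1 library was left out.

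Defence proteins rose in 9, 8 and 11 of 46 cases and fell in 19, 27 and 24 on days 3, 6 and 9 (10 and 19 on day 3 adjusted over the list alone), with medians of -0.10, -0.43 and -0.32 and adjusted p of 0.155, 0.220 and 0.436 from limma's camera. The median of day 9 was -0.16 among genes with a mean FPKM of at least 5. Cuticle genes rose in 22, 18 and 21 of 59 cases and fell in 18, 35 and 33 (23 and 18 on day 3 adjusted over the list alone), with medians of 0.12, -0.72 and -0.53 and adjusted p of 0.640, 0.25 and 0.708 from limma's camera. Leaving out single libraries put the cuticle median of day 3 between -0.03 and 0.12. Among genes with a mean FPKM of at least 5 the cuticle median and test of day 3 turned down (median -0.17), and the list passed as lower on days 6 and 9, with medians of -0.97 and -0.69. Within that list all 4 genes of the wax enzyme CER1 rose on each day, with medians of 3.38, 2.80 and 2.97. Antioxidant enzymes on day 3 rose in 20 of 65 cases and fell in 19 (21 and 19 adjusted over the list alone), with a median of -0.08 (-0.03 among genes with a mean FPKM of at least 5), a mean of -0.09, an upward test and an adjusted p of 0.848 from limma's camera. By limma's fry the antioxidant list passed as lower on that day (adjusted p of 0.0480). Cell cycle and histone genes on day 3 fell in 24 of 101 cases and rose in 10 (9 rose and 20 fell adjusted over the list alone; median -0.06, and 0.02 among genes with a mean FPKM of at least 5, adjusted p of 0.401 from limma's camera).

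Markers of other cell types and of RNA selection were measured beside these lists. Of 7 guard cell genes, 1, 2 and 2 rose and 3, 4 and 4 fell on days 3, 6 and 9 (medians -0.21, -1.68 and -1.85, a mean of 0.00 on day 3, adjusted p of 0.575, 0.801 and 0.727 from limma's camera): all 4 FAMA genes fell on days 6 and 9, and 2 of 3 SLAC1/SLAH anion channel genes rose. Of 7 XCP genes, known from xylem, 1, 0 and 0 rose and 1, 6 and 5 fell (medians -0.22, -0.77 and -1.25, adjusted p of 0.516, 0.151 and 0.177 from limma's camera). Genes named after the plastid genome, 86 tested of 846 in the tables, rose in 4, 3 and 2 cases and fell in 3, 13 and 20, and adjusted over the list alone in 1, 1 and 1 and in 1, 5 and 9. Their medians were -0.02 (0.33 among genes with a mean FPKM of at least 5), -0.25 and -0.37, the mean of day 3 was 0.03 with an upward test, the test of day 6 also pointed up with the deposited values and down with median-ratio scaling and among genes with a mean FPKM of at least 5 (median -0.49), and adjusted p were 0.873, 0.888 and 0.689 from limma's camera.

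The step from day 3 to day 6 asks whether the changes against day 0 differed between these days. Most photosynthesis transcripts fell further in this step: LHCB1 Pag.B05G002421.v3.1 went from 275 ± 111 to 1.22 ± 0.839 FPKM (SD, n = 3), rbcS Pag.B04G001039.v3.1 from 133 ± 2.38 to 7.35 ± 0.447 and por Pag.B01G004254.v3.1 from 61.6 ± 1.86 to 0.650 ± 0.305. GOLS Pag.B08G001455.v3.1 rose from 30.3 ± 1.05 to 639.7 ± 14 FPKM and WHY1 from 703 ± 7.22 to 14435 ± 184 FPKM. Of the named genes that had risen most by day 3, crtZ fell from 94.7 ± 6.94 to 48.1 ± 0.208 FPKM, while NCED Pag.B11G000660.v3.1 rose further, to 183 ± 7.50. limma called 29560 genes, 10453 higher and 19107 lower on day 6, of which 9276 changed by at least 1 on the log2 scale. The values did not overlap for 75.1% of tested genes, where chance gives 10%. The median of all genes was -0.22, moved by 0.21 to 0.00 with median-ratio scaling. That scaling gave 14578 higher and 14465 lower genes, 50.2% higher where the deposited values gave 35.4%.

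The step from day 6 to day 9 was smaller. MIOX Pag.A08G001073.v3.1, a myo-inositol oxygenase, rose from 33.8 ± 0.649 to 73.0 ± 3.19 FPKM, having been at 103 ± 1.86 on day 0, and a methionine gamma-lyase (Pag.B03G002076.v3.1) rose from 364 ± 8.13 to 1077 ± 91.2 FPKM. Rises were also called for the acetolactate synthase small subunit ilvH (Pag.A10G001924.v3.1, 0.920 ± 0.0436 to 5.03 ± 0.491 FPKM), REEP5_6 (Pag.B12G001219.v3.1, 12.2 ± 0.423 to 23.4 ± 0.935) and DCR (Pag.A12G000013.v3.1, 1.70 ± 0.0458 to 6.46 ± 0.585), the last sharing all its values with another gene model. An ethylene-responsive factor (EREBP, Pag.A14G001275.v3.1) fell from 67.2 ± 1.1 to 28.6 ± 0.461 FPKM, with falls too for LAS1 (Pag.B09G000651.v3.1, 593 ± 7.95 to 341 ± 9.20), the transcription factor RAV (Pag.B08G001291.v3.1, 98.2 ± 2.81 to 52.5 ± 0.928), the transporter NPF2/NRT1 (Pag.B17G000921.v3.1, 116 ± 0.570 to 55.8 ± 1.75) and the superoxide dismutase SOD2 (Pag.B15G000387.v3.1, 82.1 ± 1.57 to 44.5 ± 2.05). Adjusted p from limma for these 10 genes were at most 1.41e-06. limma called 8831 genes, 5275 higher and 3556 lower on day 9, and 328 of them changed by at least 1 on the log2 scale. With median-ratio scaling 4136 were higher and 4888 lower, so 45.8% of calls were higher where the deposited values gave 59.7%, and values did not overlap for 37% of tested genes, where chance gives 10%.

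Genes called on several days mostly moved the same way. The counts below use the deposited values, and none with median-ratio scaling are given here. As that scaling moved the median of all genes by 0.21 on day 6 and 0.17 on day 9, shared falls and small opposite changes are to be read against that shift. Of the genes called on both day 3 and day 6, 6365 were higher and 8710 lower on both, and 2052 went in opposite directions. For days 3 and 9 these numbers were 6391, 8462 and 2284, and for days 6 and 9 they were 10907, 17435 and 166. Independent lists of these sizes would share 2682 higher and 4886 lower genes for days 3 and 6, 2842 and 4713 for days 3 and 9, and 3675 and 8919 for days 6 and 9. On all 3 days 6002 genes were higher and 8287 lower, against 829 and 2245 for independent lists. In 20 simulations of unchanged groups set against the same controls the mean overlap was 0. At most 1 gene per day was called in each of these simulations. The overlap of 0 was thus fixed in advance and does not measure what the shared controls bring. The covariance of log2 changes was 0.620 for days 3 and 6, 0.608 for days 3 and 9 and 1.75 for days 6 and 9, beside simulated covariances of 0.0226, 0.0224 and 0.0225. The simulated covariances estimate what the shared controls bring, and they were small beside the observed ones. The correlations across genes were 0.705, 0.692 and 0.969, beside 0.506, 0.499 and 0.504 in the simulation. In unchanged groups the shared controls are the only source of correlation. The simulated correlations are thus no baseline for groups that did change. The 3 control libraries cannot be split into parts of at least 2, so part of the excess in overlap may come from the shared controls. How much of the overlap that is was not measured.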

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

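The tests of lists between days, the test of depth on larger changes, the test of ribosome biogenesis and the scaling of named genes in every comparison were chosen only after the result was seen. The comparisons of days and the main alternatives were fixed before the data were examined. The other tests of explanations in this part weigh patterns found in the data. They include those for the cytosolic ribosomal proteins, a pattern that came from the tests of lists between days. These tests of explanations therefore cannot be counted as chosen before the patterns were seen.

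The change against day 0 differed between days 6 and 3 for 29560 genes, and between days 9 and 6 for 8831, by limma's test of the difference itself. Among the 65 genes named by rule the numbers were 61 and 34. These counts follow in part from the choice: 10 of the genes were named for the smallest adjusted p between days 9 and 6, and the others for the largest changes of all genes or of a list. In 8 of these 65 genes the change was called in opposite directions on different days: LHCB7, psbR, PP2C;STK38 and PP2C Pag.A18G001005.v3.1 and a chalcone isomerase rose on day 3 and fell on days 6 and 9, PRK fell on day 3 and rose later, the acetolactate synthase subunit ilvH rose on days 3 and 9 and fell on day 6, and EREBP fell on days 3 and 9 and rose on day 6. With median-ratio scaling the fall of PP2C Pag.A18G001005.v3.1 on day 6 turned to 0.02 and was lost, and the rise of the chalcone isomerase on day 3 was lost.

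Lists that moved between days 3 and 6 by limma's camera, adjusted over 64 tests, were led by the photosystem (median -3.03, 65 of 67 falling, adjusted p of 4.19e-19) and antenna genes (-3.69, 48 of 49 falling). Lists that also passed as lower on day 6 were carbon fixation (median -2.02, 17 of 18 falling, 1 rising), chlorophyll synthesis (-1.71, 40 of 48 falling, 5 rising) and organelle-type ribosome genes (-0.88, 119 of 153 falling, 2 rising). Passing as lower too were aquaporin (-0.73, 45 of 64 falling, 14 rising), antioxidant (-0.72, 48 of 65 falling, 11 rising) and cell cycle genes (-0.61, 70 of 101 falling, 10 rising). The osmolyte list (1.12, 26 of 38 rising, 4 falling) and chlorophyll breakdown (0.70, 12 of 16 rising, 2 falling) passed as higher. So did 3 lists of more mixed members, PP2C (0.83, 16 of 28 rising, 11 falling), flavonoid (0.67, 14 of 23 rising, 6 falling) and ethylene genes (0.43, 27 of 49 rising, 17 falling). With an estimated correlation the osmolyte and organelle-type ribosome lists passed, at an adjusted p = 0.00609 and an adjusted p = 0.0286; for the other 11 it lay between 0.0767 and 0.229.

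Between days 6 and 9 cytosolic ribosomal proteins rose in 324 of 427 cases and fell in 0 (median 0.28, adjusted p of 7.61e-34 from limma's camera, adjusted p = 0.0603 with an estimated correlation). The cuticle list also passed as higher, with 30 of 59 genes rising and 1 falling (median 0.35). Lists that passed as higher with fewer members called as rising than left uncalled were aquaporin (0.20, 25 of 64 rising, 2 falling), carbon fixation (0.20, 7 of 18 rising, 1 falling), defence (0.18, 18 of 46 rising, 1 falling) and lignin genes (0.17, 39 of 121 rising, 9 falling). The same held for heat shock (0.14, 28 of 103 rising, 2 falling), circadian clock (0.14, 14 of 34 rising, 3 falling) and organelle-type ribosome genes (0.13, 33 of 153 rising, 6 falling). Chlorophyll breakdown (-0.25, 10 of 16 falling, 0 rising), ethylene (-0.10, 15 of 49 falling, 4 rising) and glutathione transferase genes (-0.05, 23 of 61 falling, 9 rising) passed as lower. With an estimated correlation cuticle, aquaporin, heat shock, chlorophyll breakdown, ethylene and glutathione transferase genes passed, at an adjusted p between 0.0268 and 0.0366, and carbon fixation, defence, lignin, organelle-type ribosome and clock genes did not, at an adjusted p between 0.182 and 0.348. The clock list also no longer passed with median-ratio scaling (adjusted p of 0.0683 from limma's camera).

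More genes differed from day 0 on days 6 and 9 (31292 and 31317) than on day 3 (19446). A few abundant genes taking more of the FPKM total would shift all others, but with median-ratio scaling the count of day 6 was still 1.62 times that of day 3. For sequencing depth, the measure first written down, the share changed on day 6 over that on day 3 among genes with a mean of at least 20 FPKM, gave 1.25 but could not have passed its bound of 1.5, since the share on day 3 allowed 1.43 at most; its replacement, on changes of at least 1 on the log2 scale among the same genes, gave 2.72 and argues against depth. A batch per day cannot be told apart from drought, as 0 batches in the labels hold libraries of more than 1 day. The length of the drought stays open with it and was not tested apart. The time that passed cannot be told apart from drought either, as no plants without drought were sampled on the later days.

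For 121 tested genes 1 library was listed at 0 and another of the same day at 20 FPKM or more, 244 such values at 0 in all, GLRX Pag.A08G000263.v3.1 among them. No library held more than 10.7% of these values. That share cannot exclude a mislabelled library, since a gene high only in that library puts the values at 0 in the others. The r between libraries argues against a swap between days, being at least 0.969 within a day and at most 0.966 between days. Reads shared between near-identical copies may explain part: among 24 such genes that share a KO name with others, the namesakes gained at least 50% of the missing FPKM in 33.3%, which leaves this open. No biological explanation was tested.

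The higher level of cytosolic ribosomal proteins on day 9 than on day 6 was weighed too. It was not a matter of a few abundant genes taking more of the FPKM total, as the median was 0.23 with median-ratio scaling. The rise was also not confined to a few copies, as 324 of 427 members were called higher by themselves. That count and the 97.2% that were higher describe the pattern itself and add no separate test. A batch per day cannot be told apart, with 0 batches holding libraries of both days. Ribosome production resuming by day 9 stays open: the ribosome biogenesis pathway, which shares 0 genes with the list, had a median of 0.15 from day 6 to day 9 (46 of 183 genes rising, 6 falling, adjusted p of 0.00390 from limma's camera, adjusted p = 0.128 with an estimated correlation). From day 3 to day 6 that pathway did not pass as lower, with a median of -0.03, 48 genes rising and 56 falling and an upward test (adjusted p of 0.253 from limma's camera), so a fall in that step was not shown. The cytosolic ribosome list did not pass in that step either (median -0.14, adjusted p of 0.630 from limma's camera), having already passed as lower on day 3 against day 0. The step thus cannot settle whether the pathway fell earlier, and its change against day 0 was not weighed here.

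Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. In each of the 5 comparisons 1 split, the real one, gave as many called genes. Every other split mixes libraries of both days, which puts the difference between days into the spread. Low counts in those splits were thus fixed in advance and cannot weigh chance. The real counts were 19446, 31292 and 31317 for days 3, 6 and 9 against day 0, 29560 for day 6 against day 3 and 8831 for day 9 against day 6, and the highest of the other splits gave 5, 2, 3, 4 and 6.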

How the results depend on the processing

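The setting without genes that share values, and the scaling of named genes in all 5 comparisons, were chosen only after the result was seen; the others were chosen beforehand. A minimum log2 change of 1 left 3517, 13230 and 13181 genes for days 3, 6 and 9 against day 0, 9276 for day 6 against day 3, 328 for day 9 against day 6 and 2801 in the overlap of all 3 days, by construction fewer. An estimated correlation left 17 of the 56 list calls, and the cause was not tested. Leaving out each library in turn gave between 16797 and 17710 genes on day 3, 29502 and 30246 on day 6, 29530 and 30400 on day 9, 28208 and 28364 for day 6 against day 3, and 6559 and 7746 for day 9 against day 6, and between 55 and 57 list calls. Of the 56 list calls 54 were kept in all 12 of these fits; starch and sugar on day 3 was lost without the first library of day 3, and PYL receptors on day 9 without the second library of day 0. A pseudocount of 0.1 gave 18456, 31234, 31125, 29437 and 8775 genes in the order above, no filter 20343, 34964, 35170, 31797 and 8206, and fits to 6 libraries 18982, 30495, 30416, 27841 and 6869, the last with 35311 genes tested. Median-ratio scaling kept 55 list calls and ended that of lignin on day 9. A mean of at least 5 FPKM left 90 list tests with 57 calls, 48 of the 56 and 9 more (lignin on days 3 and 6, CYP707A, cuticle and clock genes on days 6 and 9, and aquaporins on day 6), and the cause was not tested. As the mean covers the drought libraries too, the changes themselves help to decide which members stay. Genes without shared values numbered 39956 and gave 19163, 30805, 30846, 29103 and 8715 calls.

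The replicate numbers do not pair the libraries: 3 of 12 libraries best matched their own number in the other days, and r between same-numbered libraries, each taken as a difference from its day's mean across genes, lay between -0.0268 and 0.0381. A replicate block gave 18880, 31079, 31120, 29313 and 8084 genes and 56 list calls.

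Among the genes named by rule, 1026 values were recomputed under other settings in the comparison that named each gene, with 998 of the same direction and call, 28 no longer called and 0 reversed. The genes were named from these same libraries for large changes or small adjusted p. That most calls were kept thus follows in part from the choice. The 28 values no longer called concerned GLRX, LHCB7, LHCB2, ABF Pag.A10G002611.v3.1 and groEL Pag.A10G001529.v3.1 on day 3, and the cause was not tested. With median-ratio scaling in all 5 comparisons, RAV and PP2C Pag.A18G001005.v3.1 turned on day 6, and 1, 0, 1, 1 and 2 calls were lost in the order above. Tests on read counts were not run, as no counts or gene lengths were used here.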

Other observations

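The pathway tests in this part were chosen only after the result was seen. Of 130 pathways named in the tables, 22, 29 and 27 passed limma's camera on days 3, 6 and 9, and 3, 3 and 4 with an estimated correlation. On day 3 genes of unsaturated fatty acid synthesis rose in 31 of 48 cases and fell in 5 (median 0.43, adjusted p of 4.20e-06 from limma's camera, adjusted p = 0.0799 with an estimated correlation). Fatty acid degradation rose in 62 cases and fell in 14 (median 0.28, adjusted p of 8.98e-06 from limma's camera, adjusted p = 0.0849 with an estimated correlation). Cutin, suberine and wax synthesis rose in 26 cases and fell in 8 (median 0.39, adjusted p of 0.00160 from limma's camera, adjusted p = 0.0903 with an estimated correlation). The cuticle list fixed beforehand did not pass on that day, with 22 of 59 genes rising and 18 falling (adjusted p of 0.640 from limma's camera) and a median of 0.12 that turned to -0.17 among genes with a mean FPKM of at least 5. Galactose metabolism, which holds the raffinose sugars, rose in 62 cases and fell in 29 (median 0.25, adjusted p of 0.00147 from limma's camera, adjusted p = 0.0336 with an estimated correlation). Motor proteins fell in 93 of 174 cases and rose in 18 (median -0.29, adjusted p of 9.02e-06 from limma's camera, adjusted p = 0.0418 with an estimated correlation).

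On days 6 and 9 the tricarboxylic acid cycle rose in 73 and 79 of 132 cases and fell in 38 and 33 (medians 0.34 and 0.42), with adjusted p of 3.06e-04 and 4.19e-05 from limma's camera and an adjusted p = 0.0249 with an estimated correlation on both days. Brassinosteroid synthesis fell in 26 of 27 cases on both days (medians -1.48 and -1.26, adjusted p of 4.49e-05 and 1.97e-05 from limma's camera, adjusted p = 0.200 and 0.180 with an estimated correlation). Zeatin synthesis rose in 14 of 19 cases and fell in 4 on day 6 (median 1.04, adjusted p of 0.00297 from limma's camera, adjusted p = 0.0849 with an estimated correlation). Base excision repair fell in 72 of 101 cases on day 6 and rose in 10 (median -0.66, adjusted p of 0.00798 from limma's camera, adjusted p = 0.152 with an estimated correlation).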
